A study of Folsomia candida with 168 samples.

How the data were processed

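RNA of whole bodies of Folsomia candida was measured in 168 libraries, each from a pool of 70 animals, with paired reads of 150 bp from 1 µg of RNA and 10 M reads aimed at per library, per the labels' protocols. The deposited values are estimated counts per gene, made by the authors from the reads before deposit. Trim Galore, Salmon 1.4.0 and DESeq2 1.28.1 are named per the submitters' processing notes, and the reference transcripts used are not given in the sources used here. The table held 28617 genes, of which 1652 had no count in any library, and every column matched a sample. Values were taken as whole counts, with any decimals dropped. Compounds, doses and experiment were taken from the labels, which gave 56 conditions of 3 libraries. Library numbers 1 to 3 within a condition follow the order of listing and are only names.

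Totals per library averaged 8518520 counts in experiment 1 and 8490040 in experiment 2, with a coefficient of variation of 2.91% over all libraries. The 10 most abundant genes held 7.12% to 18.7% of a library's counts. Factors of the trimmed mean of M values (TMM) lay between 0.853 and 1.13. No pair of libraries looked like 1 library sequenced again. Over 9268 genes with a mean of at least 100 counts, the 168 pairs within conditions differed by at least 3.90 times and at the median by 19.2 times the variance of counting, and the 6804 other pairs within experiments by at least 2.83 times. Counting intervals of ratios cover counting error only. The labels do not show that the libraries of a condition came from separate cultures, so p values measure the spread between these samples.

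Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the condition as group, which left 17071 genes in experiment 1, 16985 in experiment 2, 16744 in both and 17474 in the joint fit of all libraries. Trends came from a model with a linear term for the TU of each compound of an experiment, and the slope difference of 2 compounds is a contrast of these terms. Departure from additivity is the product of both doses added to this model. The difference of the imidacloprid slopes between experiments came from a joint fit with separate intercepts and slopes per experiment. Comparisons at 1 TU and at matched doses used 1 coefficient per condition and all 84 libraries of the experiment for the dispersion. Tests were edgeR's quasi-likelihood F-tests with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Standard errors (SE) are the size of the log2 coefficient over the square root of its F value. The 95% intervals of the log2 coefficients are normal intervals from these. Both are approximate, above all for genes with few counts. Where a group had no counts the fold is a lower bound from a floor of 3 counts over the group. Comparisons, tests and the first set of alternatives were fixed before the data were examined.

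Genes were named by a rule fixed at the same time. Among genes with an adjusted p below 0.05 and a mean of at least 5 CPM over the experiment, the 2 with the largest log2 change in each direction were named, for trends only if the sign was the same in the 1 TU comparison of the compound. Genes rising with imidacloprid in both experiments and with clothianidin were ordered by the smallest of their 3 slopes. Gene lists by function had been planned, but 0 of the 28617 identifiers occurred among the 27231 genes of the RefSeq table of assembly ASM221717v1 used here, so no list was formed or tested.

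Overlaps of trends were compared with the product of list lengths over the number of genes tested in both, and with 99 fits in which the doses were reassigned at random among the libraries of an experiment. Residual components are principal components of log2 CPM around the condition means. As a covariate, the first residual component has the same mean in every condition, so it cannot account for a state difference between conditions. The state of a library is its projection on the 2 leading residual directions. The on-off genes were found from the data of experiment 2, as genes that correlate above 0.8 with the gene of largest weight on the residual component of rank 3, and a library counted as high if it lay above the largest gap in their summed CPM. Every comparison was also refitted on regrouped libraries, 99 random regroupings for trends and product terms, 59 for the difference between experiments, and the 9 other splits of 3 against 3 libraries.

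The alternatives were size factors by relative log expression, no low-count filter, DESeq2 1.42.0 with its Wald test, the first residual component as a covariate, conditions at 1 TU left out, controls left out, any exposure against none, dose as 6 classes, the product of doses in the model, single-compound series, only the 2 groups compared, and 1 library left out. For trends the last was done by leaving out 28 libraries at a time, those with the same number in every condition. Added after the values were seen were the 2 state components as covariates, the place of a library in the listing as a block, and fits without the libraries far from the rest, without the libraries high in the on-off genes, and on counts summed per condition. The count of genes called under 11 alternatives joins relative log expression, no filter, DESeq2, both covariate fits, the fits without far libraries, without high on-off libraries and without 1 TU, and the 3 fits without 28 libraries.

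The pipeline was tested on simulated data with 200 changed genes per comparison and between 16727 and 16808 genes fitted. For slopes of 0.5, 1 and 2 log2 per TU, edgeR recovered 61.2%, 89.6% and 100% of changed genes for imidacloprid in experiment 1, 49.3%, 88.1% and 100% for clothianidin, 46.3%, 82.1% and 98.5% for imidacloprid in experiment 2, and 31.3%, 85.1% and 98.5% for cyproconazole. For product terms of 1, 2 and 4 it recovered 26.9%, 74.6% and 97.0% in experiment 1 and 29.9%, 59.7% and 92.4% in experiment 2. For changes of 1, 2 and 3 at 1 TU it recovered 49.3%, 79.1% and 89.4% with clothianidin and 19.4%, 68.7% and 92.4% with cyproconazole. For differences of 0.5, 1 and 2 between the experiments' imidacloprid slopes it recovered 29.9%, 79.1% and 92.4%. Between 2.44% and 9.71% of the genes called were false. Genes were simulated independently, without the variation that genes share between the real libraries. These shares and the recovery may therefore not hold for the real data.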

Results

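Folsomia candida, a soil-dwelling springtail that reproduces without males, was exposed to pairs of pesticides in soil, and RNA from whole bodies was sequenced. Each library came from a pool of 70 animals. The 168 libraries fall into 56 conditions of 3 libraries each, 28 conditions in each of 2 experiments. Experiment 1 combined the neonicotinoid insecticides imidacloprid and clothianidin, and experiment 2 combined imidacloprid with the triazole fungicide cyproconazole. Doses were set in toxic units (TU), where 1 TU is the concentration that lowers juvenile counts by 50%. It corresponded to 0.4 mg imidacloprid, 0.24 mg clothianidin or 250 mg cyproconazole per kg dry soil. All pairs of 0, 0.2, 0.4, 0.6 and 0.8 TU were made up, and 1 TU was used for each compound alone and for both compounds together. The series asks which transcripts mark exposure to pesticides robustly when the pesticides come as mixtures. The libraries held between 7756892 and 9208853 counts (mean 8504280, SD 247712, n = 168), and between 18530 and 20053 genes had at least 1 count in a library. After removal of low counts, 17071 genes were tested in experiment 1 and 16985 in experiment 2. Genes carry the identifiers of the deposited table, which does not pair them with names, so no function is given for any of them. Unless said otherwise, genes are named for the largest changes among those averaging at least 5 CPM over the experiment, for trends with the same sign at 1 TU, and some other genes changed more. Slopes are log2 changes per TU with the other compound's dose in the model, fitted over the 84 libraries of an experiment. Adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene is said to rise, fall or change where this value was below 0.05. Levels are counts scaled to library size (CPM), given as mean ± SD over the 3 libraries of a condition.

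With imidacloprid in experiment 1, Fcan01_17957 rose from 62.8 ± 16.8 CPM in untreated animals to 209 ± 80.4 CPM at 0.2 TU and 570.4 ± 65.0 CPM at 1 TU of imidacloprid alone (n = 3 each). Its slope of 2.55 (SE 0.155, 95% interval 2.25 to 2.86) is a 5.87-fold rise per TU (edgeR adjusted p = 7.07e-24). Fcan01_10767 rose from 1.01 ± 0.494 to 13.5 ± 0.393 CPM, with a slope of 2.13 (SE 0.192, edgeR adjusted p = 1.77e-14). Fcan01_07162 dropped from 17.5 ± 4.36 to 5.61 ± 2.27 CPM, a 3.99-fold fall per TU (interval of the log2 slope -2.44 to -1.55, edgeR adjusted p = 3.80e-10). Fcan01_22151 had a slope of -1.70 (SE 0.369, edgeR adjusted p = 0.00311), from 25.7 ± 26.2 CPM in untreated animals to 4.38 ± 1.57 CPM at 1 TU. In all, 63 genes rose and 324 fell (127 and 242 with the 2 state components as covariates), with median slopes of 0.54 among the rising and -0.92 among the falling genes. These 387 genes were also fitted with the doses of both compounds as classes over the 84 libraries. In the called direction they stood a median of 0.51, 0.69, 0.75, 0.87 and 0.72 log2 units from 0 TU of imidacloprid at 0.2, 0.4, 0.6, 0.8 and 1 TU. They had been chosen on the same libraries. The count moved to 764, 63 and 84 without the libraries numbered 1, 2 and 3 of every condition, and 37 of the 387 genes (15 rising, 22 falling) passed in the same direction under each of 11 alternative settings, a count defined after the alternatives had been seen. Fcan01_22151 lost its call without the libraries numbered 1 (slope -1.51) or 2 (slope -1.45), and it, Fcan01_10767 and Fcan01_07162 lost theirs when the fit used the imidacloprid-only series of 18 libraries.

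**Figure D1:**
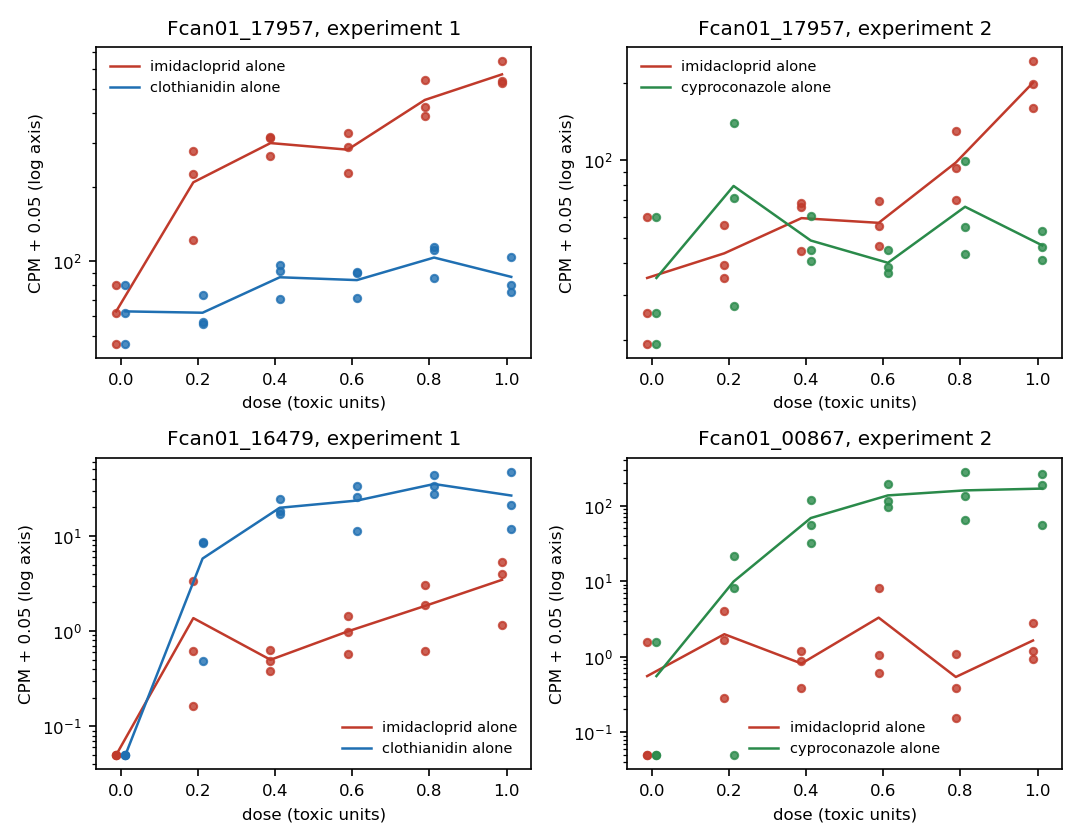
CPM plus 0.05 (log axis) against the dose of a single compound in toxic units for Fcan01_17957 in both experiments, Fcan01_16479 in experiment 1 and Fcan01_00867 in experiment 2. Points are libraries, lines join the means of 3 libraries, and Fcan01_17957 reaches 570.4 CPM at 1 TU of imidacloprid against 86.6 CPM at 1 TU of clothianidin.

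By the linear trends clothianidin changed more genes than imidacloprid. With any exposure against none, imidacloprid gave more genes than the linear trend of either compound. This sets unlike fits side by side and does not rank the compounds, since the clothianidin count with any exposure is not given here. Fcan01_22151 fell along the clothianidin doses with a slope of -2.93 (SE 0.377, edgeR adjusted p = 2.00e-08), to 1.90 ± 0.762 CPM at 1 TU. Fcan01_14587 fell with a slope of -2.25 (SE 0.304, edgeR adjusted p = 7.12e-08) and stood at 76.6 ± 77.1 CPM in untreated animals and at 4.97 ± 2.34 CPM at 1 TU (n = 3). Fcan01_25788 rose with a slope of 3.34 (SE 0.578, edgeR adjusted p = 2.03e-05) and Fcan01_06702 with a slope of 2.94 (SE 0.543, edgeR adjusted p = 6.35e-05). Both rising genes varied widely at 1 TU, where Fcan01_25788 was at 118 ± 184 CPM and Fcan01_06702 at 141 ± 230 CPM against 0.806 and 1.16 CPM in untreated animals. Over all genes 898 rose and 794 fell, with median slopes of 0.56 and -0.74. In the fit of dose classes over the 84 libraries, the 1692 genes stood a median of 0.16, 0.30, 0.46, 0.58 and 0.41 log2 units from 0 TU of clothianidin. These medians are in the called direction at the 5 rising doses of clothianidin. Without the libraries numbered 2 and 3 of every condition 857 and 593 genes passed, and 286 genes (175 rising, 111 falling) passed under each of the 11 alternatives. Of 17 alternatives the 2 rising genes lost their calls in 3 (Fcan01_25788, log2 values from 1.93 to 4.94) and 5 (Fcan01_06702, 0.54 to 5.75). With any exposure against none the log2 changes of Fcan01_25788 and Fcan01_06702 were 1.93 and 0.54 (edgeR adjusted p = 0.0629 and 0.697), and without the libraries numbered 3 their slopes were 2.34 and 0.96 (edgeR adjusted p = 0.0883 and 0.404). Fcan01_25788 also lost its call without the 1 TU conditions (1.95), and Fcan01_06702 without the libraries far from the rest (1.00), without those high in 302 genes that are near silent in most libraries (1.01) and by DESeq2, which gave it no adjusted p (2.96).

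Imidacloprid and clothianidin are both nitroguanidine neonicotinoids. Imidacloprid carries a chloropyridinyl group and a closed imidazolidine ring, while clothianidin carries a chlorothiazolyl group and an open chain. At matched toxic units, with concentrations in soil that differ, their responses separated in several genes. The slope of Fcan01_17957 was 2.97 higher for imidacloprid than for clothianidin (SE 0.205, interval 2.57 to 3.38, edgeR adjusted p = 2.22e-20), and that of Fcan01_10767 was 2.51 higher (SE 0.256, interval 2.00 to 3.01, edgeR adjusted p = 6.38e-12). Fcan01_16479 lay the other way, with a difference of -5.13 (SE 0.561, interval -6.23 to -4.03, edgeR adjusted p = 9.83e-11). It had no count in untreated animals of experiment 1 and reached 26.5 ± 18.1 CPM at 1 TU of clothianidin alone (683 counts, at least 218-fold higher) against 3.41 ± 2.11 CPM at 1 TU of imidacloprid alone (87 counts, at least 28.7-fold higher). Fcan01_25788 differed by -3.69 (SE 0.662, interval -4.99 to -2.39, edgeR adjusted p = 6.12e-05), but of 13 alternatives Fcan01_25788 lost this call in 3, which were those without the libraries numbered 3 (-1.72, edgeR adjusted p = 0.442), without the libraries far from the rest (-1.88) and without those high in 302 genes that are near silent in most libraries (-1.84). Among 977 genes whose slopes differed, 170 had the higher slope for imidacloprid and 807 the higher slope for clothianidin, and 102 of them (12 and 90) passed under each of the 11 alternatives. With the 2 state components as covariates the split was near even, at 347 and 362. The count was 393 without the libraries numbered 2 and 123 without those numbered 3. Other genes gave no call of a difference. For Fcan01_17273, which rose with both compounds, the difference was 0.42 (interval 0.12 to 0.72, edgeR adjusted p = 0.0889), and for Fcan01_20354, which rose with imidacloprid, it was 0.26 (interval -0.11 to 0.64, edgeR adjusted p = 0.395). These genes were singled out after their values had been seen.

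Comparisons at single doses set 3 libraries against 3, and the main edgeR fit called few genes. DESeq2 called more at each dose, by little at 0.2 TU, and so did the fits with residual or state covariates. Those counts are given in the section on processing, and that of DESeq2 at 0.2 TU below. Fcan01_17957 was higher with imidacloprid than with clothianidin at each of the 5 doses. The difference was 1.75 at 0.2 TU (SE 0.283), 1.80 at 0.4 TU (interval 1.25 to 2.36), 1.75 at 0.6 TU (SE 0.282), 2.12 at 0.8 TU (interval 1.56 to 2.68) and 2.72 at 1 TU (interval 2.15 to 3.29), with edgeR adjusted p values of 0.00102, 0.000504, 0.000976, 8.72e-06 and 5.43e-09. At 0.2 TU 3 genes differed, all higher with imidacloprid, among them Fcan01_08638 by 1.55 (edgeR adjusted p = 0.0251). At 0.4 TU 5 genes differed, and Fcan01_16479 was lower with imidacloprid by a log2 difference of -5.42 (interval -7.38 to -3.45, edgeR adjusted p = 0.00891), as was Fcan01_15558 at -1.53 (edgeR adjusted p = 0.0121). At 0.6 TU 7 genes differed, with Fcan01_08638 at 1.58, Fcan01_16479 at -4.63 and Fcan01_05160 at -1.28 (edgeR adjusted p = 0.0172, 0.0363 and 0.0442). At 0.8 TU 25 genes differed, 9 higher and 16 lower with imidacloprid, including Fcan01_13586 at 2.69, Fcan01_16479 at -4.29 and Fcan01_17604 at -2.37 (edgeR adjusted p = 0.0129, 0.0199 and 0.0406). At 1 TU 9 genes differed, with Fcan01_10767 at 2.14 (interval 1.34 to 2.94), Fcan01_08740 at -2.10 and Fcan01_23397 at -0.76 (edgeR adjusted p = 0.00640, 0.0107 and 0.0404).

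Most of these single-dose calls were lost when any of several libraries was left out, mostly with a difference of similar size. At 0.2 TU the call of Fcan01_17957 was lost without imidacloprid library 3 (1.49) or clothianidin library 2 (1.68) or 3 (1.67), while its calls at the 4 higher doses withstood each removal. Fcan01_08638 lost its call at 0.2 TU without imidacloprid library 1 (1.53) or 3 (1.30) or clothianidin library 1 (1.47), 2 (1.62) or 3 (1.54), and at 0.6 TU without imidacloprid library 3 (1.39) or clothianidin library 1 (1.35) or 3 (1.48). Fcan01_16479 lost it at 0.4 TU without imidacloprid library 1 (-5.40) or 3 (-5.22), at 0.6 TU without imidacloprid library 1 (-4.33), 2 (-5.01) or 3 (-4.62) or clothianidin library 2 (-4.56) or 3 (-4.29), and at 0.8 TU without imidacloprid library 1 (-4.32) or 2 (-3.87) or clothianidin library 1 (-4.32) or 3 (-4.10). Fcan01_15558 lost it without imidacloprid library 1 (-1.36) or 3 (-1.36) or clothianidin library 2 (-1.39) or 3 (-1.48). Fcan01_05160 lost it without imidacloprid library 1 (-1.13), 2 (-1.42) or 3 (-1.32) or clothianidin library 2 (-1.11) or 3 (-1.31). Fcan01_13586 lost it without imidacloprid library 1 (2.47) or clothianidin library 1 (2.52) or 3 (2.66). Fcan01_17604 lost it without imidacloprid library 1 (-2.28), 2 (-2.44) or 3 (-2.44) or clothianidin library 1 (-2.57) or 2 (-1.64). At 1 TU, clothianidin library 3 carried most of the difference of Fcan01_08740 and Fcan01_23397, which stood at -0.33 and -0.34 without it, and both also lost the call without imidacloprid library 1 (-2.04 and -0.64), 2 (-2.02 and -0.86) or 3 (-2.21 and -0.78). The counts moved likewise. The 3 genes at 0.2 TU became 1 without imidacloprid library 1 or clothianidin library 1 and 0 without imidacloprid library 3 or clothianidin library 2 or 3. The 0 counts are edgeR's, and DESeq2 on all libraries called 4. In edgeR's fit of all libraries 971 of 17071 genes had an unadjusted p below 0.05, a share near that which chance would give. The 5 genes at 0.4 TU became 1 without imidacloprid library 1 or 3, 12 without imidacloprid library 2, and 2 without clothianidin library 2 or 3. The 7 genes at 0.6 TU became 2 without imidacloprid library 1 or 2 or clothianidin library 2, 1 without imidacloprid library 3 or clothianidin library 3, and 4 without clothianidin library 1. The 25 genes at 0.8 TU became 4 and 6 without imidacloprid library 1 and 2, and 3 and 9 without clothianidin library 1 and 3. The 9 genes at 1 TU became 63 and 61 without clothianidin library 1 and 2.

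In mixtures of imidacloprid and clothianidin, 97 genes departed from additivity of the 2 doses on the log2 scale, 66 with a positive and 31 with a negative product term (71 and 75 by DESeq2). Fcan01_16479 had a negative term of -4.71 per squared TU (SE 1.16, edgeR adjusted p = 0.0285). Clothianidin alone raised it to 35.1 ± 8.17 CPM at 0.8 TU, and the plot of levels over both doses shows lower levels wherever imidacloprid was added to clothianidin. Its imidacloprid slope over the experiment was -2.19 (edgeR adjusted p = 0.00141). At 1 TU of both compounds it stood at 4.04 ± 2.62 CPM against 26.5 ± 18.1 CPM with clothianidin alone (n = 3 each). Fcan01_00925 had a positive term of 3.60 (SE 0.621, edgeR adjusted p = 0.000776). It was at 39.9 ± 16.4 CPM in untreated animals, and at 2.80 ± 0.677, 3.76 ± 0.440 and 3.88 ± 1.63 CPM at 1 TU of imidacloprid, of clothianidin and of both. Fcan01_14598 had a term of 3.54 (SE 0.896, edgeR adjusted p = 0.0373) and Fcan01_06702 one of -5.94 (SE 1.03, edgeR adjusted p = 0.000776). Of 100 regroupings of the libraries, the real one included, 9 gave at least 97 calls, and the count was 447 with the first residual component and 531 with the 2 state components as covariates, 8 without the libraries far from the rest and 7 on counts summed per condition. It was 326, 2 and 27 without the libraries numbered 1, 2 and 3, and 1 of the 97 genes passed under each of the 11 alternatives. Fcan01_00925 lost its call without the libraries numbered 2 (3.45), Fcan01_14598 without those numbered 1 (3.44), 2 (3.98) or 3 (3.29), Fcan01_06702 without 2 (-5.56) or 3 (-4.35), and Fcan01_16479 without 2 (-5.58) or 3 (-3.60). Over 13 alternatives Fcan01_14598 (2.96 to 5.66), Fcan01_06702 (-6.49 to -2.12) and Fcan01_16479 (-5.68 to -3.60) lost their calls in 6 each, and Fcan01_00925 (3.12 to 4.39) in 2.

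**Figure D2:**
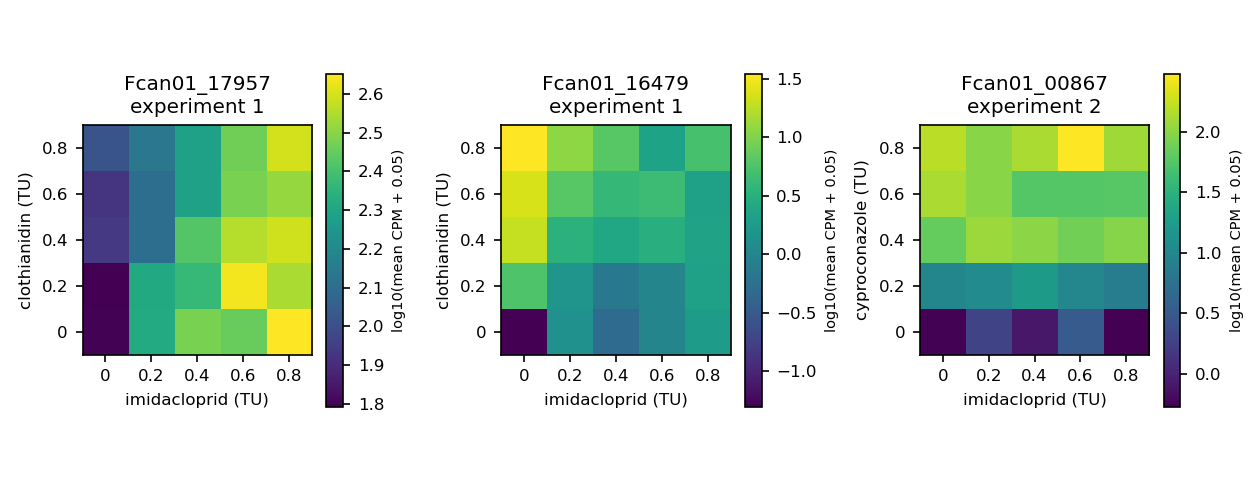
Log10 of the mean CPM plus 0.05 (colour, own scale per panel) over the factorial of both doses from 0 to 0.8 TU, 3 libraries per square, for Fcan01_17957 and Fcan01_16479 in experiment 1 and Fcan01_00867 in experiment 2. Fcan01_17957 follows the imidacloprid axis and Fcan01_00867 the cyproconazole axis, while Fcan01_16479 reaches 35.1 CPM at 0.8 TU of clothianidin without imidacloprid.

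At the highest doses of experiment 1 against untreated animals, 1 TU of clothianidin changed 1164 genes (516 higher, 648 lower), 1 TU of imidacloprid 60 (30 higher, 30 lower), and both together 170 (85 higher, 85 lower). Fcan01_16479, absent from the untreated libraries, passed in all 3 comparisons (edgeR adjusted p = 2.36e-05 with clothianidin, 0.0156 with imidacloprid and 0.00657 with both). It was at least 32.8-fold higher with both (100 counts). With imidacloprid, Fcan01_16433 was at 28.6 ± 18.5 CPM against 0.554 ± 0.512 CPM (log2 change 5.71, edgeR adjusted p = 0.0130), while Fcan01_00925 fell by 3.82 (SE 0.507, edgeR adjusted p = 1.38e-06) and Fcan01_10082 fell by 2.91 (SE 0.540, edgeR adjusted p = 0.00188) on the log2 scale. With clothianidin, Fcan01_15993 went from 39.9 ± 18.7 to 1.58 ± 0.440 CPM (log2 change -4.65, edgeR adjusted p = 5.85e-05) and Fcan01_01202 from 185.0 ± 144 to 11.8 ± 4.05 CPM (log2 change -3.97, edgeR adjusted p = 0.000456). Fcan01_21965 stood at 1.79 ± 0.578 CPM in untreated animals and between 46.2 and 1645 CPM in the 3 clothianidin libraries (log2 change 8.33, edgeR adjusted p = 0.00330). With both compounds Fcan01_22151 fell by 5.82 (SE 1.11, edgeR adjusted p = 0.00154) and Fcan01_14587 fell by 4.17 (SE 0.783, edgeR adjusted p = 0.00144), while Fcan01_06632 ranged from 0.791 to 140 CPM in the mixture libraries (log2 change 7.03, edgeR adjusted p = 0.0419).

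Untreated libraries 1 and 3 and clothianidin library 3 correlated less with the rest of the experiment than most libraries did, and without the libraries far from the rest imidacloprid gave 34 genes, clothianidin 126 (18 higher, 108 lower) and both 112 (32 higher, 80 lower). Untreated library 3 and clothianidin library 3 also carried 1692 and 1330 summed CPM of 302 genes that are near silent in most libraries. Leaving out single libraries also ended some of these calls and moved the counts. Without clothianidin library 3 the change of Fcan01_21965 was 4.83 (edgeR adjusted p = 0.0871). With imidacloprid the call of Fcan01_16433 was lost without untreated library 1 (5.88), 2 (6.51) or 3 (5.08) or imidacloprid library 2 (5.18). That of Fcan01_16479, whose fold has only a lower bound, was lost without the same libraries (edgeR adjusted p = 0.120, 0.0731, 0.0878 and 0.110). Fcan01_06632 lost its call without untreated library 1 (6.87), 2 (6.49) or 3 (8.39) or mixture library 3 (2.66). The 60 genes became 24 without untreated library 1, and 19 and 33 without imidacloprid library 2 and 3. With the first residual component as a covariate clothianidin gave more higher than lower genes (2239 and 1647). The 1164 genes became 367 without untreated library 1, and 592 and 407 without clothianidin library 2 and 3. The 170 genes became 78, 82 and 259 without untreated library 1, 2 and 3, and 105, 92 and 113 without mixture library 1, 2 and 3. When only the 6 libraries compared were fitted, edgeR called 2 genes with imidacloprid and 0 with clothianidin or both, where the fit of all libraries gave 3930 and 2222 genes at an unadjusted p below 0.05 and DESeq2 on all libraries called 1509 and 297.

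Imidacloprid in experiment 2 changed 11 genes, all rising, with a median slope of 1.32, while 20 rising and 12 falling genes were called with the 2 state components as covariates. Among those averaging at least 5 CPM, Fcan01_17957 had the largest slope, as in experiment 1. It went from 34.8 ± 21.9 CPM in untreated animals to 199.8 ± 41.6 CPM at 1 TU of imidacloprid alone (n = 3), with a slope of 1.79 (SE 0.210, interval 1.38 to 2.21, edgeR adjusted p = 3.47e-09). Fcan01_17452 rose from 27.0 ± 23.8 to 190.6 ± 45.2 CPM with a slope of 1.62 (SE 0.222, edgeR adjusted p = 6.47e-07). Of the 11 genes, 8 also rose with imidacloprid in experiment 1, where lists drawn independently would share 0.0401 genes and 99 regroupings of the libraries shared at most 1. Most regrouped lists were shorter than the real ones, which keeps their overlaps small. Conversely, of 357 imidacloprid genes of experiment 1 tested in both, 217 (60.8%) had the same sign in experiment 2. Their median slope in the called direction was 0.067 there, against 0.80 in experiment 1, where they were chosen. Besides Fcan01_17957, Fcan01_10767, Fcan01_17452 and Fcan01_08638 the 8 genes include Fcan01_16176 and Fcan01_17273, which rose with clothianidin as well. The slopes of the 8 genes spanned 0.55 to 2.55 in experiment 1 and 0.84 to 1.79 in experiment 2. With the other compounds they spanned -0.42 to 1.16 for clothianidin and 0.14 to 1.14 for cyproconazole, with 2 genes called for each. The imidacloprid slope exceeded the clothianidin slope in 5 of the 8 and the cyproconazole slope in 3 of the 8 by the tests of the differences. Product terms of the 8 spanned -1.03 to -0.44 in experiment 1 and -1.44 to -0.09 in experiment 2, and edgeR called 0 of them (lowest adjusted p = 0.186 and 0.389). Without the libraries numbered 1, 2 and 3 of every condition the 11 genes became 26, 5 and 7, and 5 of the 11 passed under each of the 11 alternatives. Of 17 alternatives Fcan01_16176 and Fcan01_17273 lost their calls in 12 and 9 (log2 values from 0.60 to 2.07 and from 0.35 to 1.05).

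The imidacloprid slopes of the experiments were also compared directly. Among 17474 genes, 20 had a higher slope in experiment 2, and none had a lower one. Of the 20, all had slopes below 0 in experiment 1, where 17 were called, 16 had slopes above 0 in experiment 2, where 2 were not tested and edgeR called 0 (the whole trend had 1353 genes at an unadjusted p below 0.05). Fcan01_24555 differed by 2.09 (SE 0.455, edgeR adjusted p = 0.0143) and Fcan01_06718 by 1.83 (SE 0.432, edgeR adjusted p = 0.0389). From untreated animals to 1 TU of imidacloprid alone, Fcan01_24555 went from 4.77 ± 0.740 to 5.33 ± 1.27 CPM in experiment 1 and from 5.28 ± 4.46 to 7.91 ± 4.27 CPM in experiment 2. Fcan01_06718 went from 6.88 ± 1.56 to 5.32 ± 0.880 CPM and, in experiment 2, from 7.36 ± 1.10 to 7.54 ± 2.28 CPM (counting interval of the ratio 0.812 to 1.24), where its slope was 1.65 (edgeR adjusted p = 0.0699). Neither gene held in every reduced data set. Without the libraries numbered 1, 2 and 3 the difference of Fcan01_24555 was 1.12, 2.23 and 2.46 (edgeR adjusted p = 0.0352, 0.445 and 0.279), that of Fcan01_06718 was -0.00240, 2.31 and 2.41 (edgeR adjusted p = 0.995, 0.250 and 0.214), and the 20 genes became 2354, 2 and 1. For the 8 genes rising in both experiments the difference spanned -0.76 to 0.67, and edgeR called 0 of them (lowest adjusted p = 0.256). For Fcan01_17957 it was -0.76 with an interval of -1.28 to -0.23.

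Cyproconazole raised Fcan01_00867 from 0.503 ± 0.872 CPM in untreated animals to 9.83 ± 10.8, 68.4 ± 44.2, 137 ± 52.5, 159 ± 108 and 168 ± 104 CPM at 0.2, 0.4, 0.6, 0.8 and 1 TU alone (n = 3 each), with a slope of 6.75 (SE 0.687, edgeR adjusted p = 1.21e-12). Fcan01_00866, the neighbouring identifier, had 2 counts in the untreated libraries and 698 at 1 TU (ratio 343, counting interval 94.6 to 2839), with a slope of 6.40 (SE 0.577, edgeR adjusted p = 9.01e-15). In a fit of the cyproconazole-only series neither Fcan01_00867 nor Fcan01_00866 was called (edgeR adjusted p = 0.278 and 0.0954). With imidacloprid alone Fcan01_00867 was at 1.59 ± 1.01 CPM at 1 TU, and in experiment 1 it lay between 1.91 and 3.22 CPM in the untreated and 1 TU conditions. Fcan01_01275 and Fcan01_18719 had slopes of -1.84 (SE 0.525, edgeR adjusted p = 0.0468) and -1.75 (SE 0.447, edgeR adjusted p = 0.0188). Over all genes 164 rose and 114 fell, with median slopes of 1.10 and -1.29, but falling genes were the majority with the first residual component (330 rising, 702 falling) or the 2 state components (417 and 615) as covariates. The 2 directions differed in how well they held, since 83 rising and 1 falling gene passed under each of the 11 alternatives. The 278 genes became 107 and 106 without the libraries numbered 2 and 3 of every condition. Without these, Fcan01_01275 lost its call (-1.37 and -2.04), as did Fcan01_18719 (-1.31 and -1.70), and with cyproconazole alone in the fit their slopes were -0.14 and -0.01. Of 17 alternatives Fcan01_01275 lost its call in 11 and Fcan01_18719 in 8.

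Against imidacloprid in the same experiment, Fcan01_00867 and Fcan01_00866 had slopes for imidacloprid that were lower by log2 differences of -7.27 (SE 0.864, edgeR adjusted p = 1.89e-09) and -7.15 (SE 0.724, edgeR adjusted p = 6.80e-12). Fcan01_08259 and Fcan01_28078 had the higher slope for imidacloprid, by 1.88 (SE 0.493, edgeR adjusted p = 0.0408) and 1.64 (SE 0.422, edgeR adjusted p = 0.0328). The slopes of 113 genes differed, 19 higher and 94 lower for imidacloprid, and 37 of these (1 higher, 36 lower) passed under each of the 11 alternatives. With the first residual component as a covariate the balance turned round, to 633 higher and 150 lower, and with the 2 state components it was 144 and 191. The first residual component cannot account for a state difference between conditions. The count was 63, 72 and 72 without the libraries numbered 1, 2 and 3. Fcan01_08259 lost its call in each of these (1.10, 2.05 and 2.35) and Fcan01_28078 without those numbered 2 (1.41) or 3 (1.33), and of 13 alternatives they lost their calls in 7 and 6. No departure from additivity of imidacloprid and cyproconazole was called. Fcan01_00867 had a product term of 0.11 (SE 2.16), Fcan01_17957 one of -0.44 (interval -1.61 to 0.74), and edgeR called 0 of 16985 genes, with 2177 at an unadjusted p below 0.05, while DESeq2 also called 0.

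At 1 TU in experiment 2, Fcan01_00867 stood at 168 ± 104 CPM with cyproconazole and at 104 ± 29.0 CPM with both compounds, log2 changes of 8.51 (SE 1.25, edgeR adjusted p = 4.73e-05) and 7.81 (SE 1.23, edgeR adjusted p = 0.000540) from untreated animals. Fcan01_00866 changed by 8.22 (SE 1.18, edgeR adjusted p = 4.73e-05) and 6.69 (SE 1.17, edgeR adjusted p = 0.00209). Cyproconazole at 1 TU raised 18 genes, and both compounds raised 13. Imidacloprid at 1 TU gave 3159 calls, 982 higher and 2177 lower. Among them Fcan01_06094 went from 1.07 ± 1.55 to 57.7 ± 16.8 CPM (log2 change 5.70, edgeR adjusted p = 0.0302), Fcan01_06093 from 0.958 ± 1.36 to 50.8 ± 21.0 CPM (5.67, edgeR adjusted p = 0.0306), Fcan01_23701 from 10.4 ± 7.29 to 1.44 ± 1.81 CPM (-2.83, edgeR adjusted p = 0.0306) and Fcan01_10135 from 8.50 ± 4.09 to 2.08 ± 1.04 CPM (-2.02, edgeR adjusted p = 0.0291). In experiment 1 Fcan01_06094 moved from 70.4 ± 38.7 to 36.7 ± 30.9 CPM at the same dose. The 3159 calls became 0 without untreated library 1 or 2, 7404 without untreated library 3, and 5 and 3 without imidacloprid library 1 and 2. They also became 0 when only the 6 libraries compared were fitted and 5 without the filter on low counts. The 0 counts are edgeR's, with 6254 genes at an unadjusted p below 0.05 in the fit of all libraries, where DESeq2 called 4239.

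The calls of the named imidacloprid genes were lost when any of several libraries was left out. Without imidacloprid library 1 and 2 and untreated library 1 and 2, in this order, the change of Fcan01_06094 was 5.63, 5.87, 5.20 and 8.22, that of Fcan01_06093 5.45, 5.93, 5.18 and 8.03, that of Fcan01_23701 -4.67, -2.50, -2.26 and -2.78, and that of Fcan01_10135 -2.10, -1.72, -1.88 and -1.74, none of them called. Fcan01_23701 also lost its call without imidacloprid library 3 (-2.35). With the 2 state components as covariates the changes of Fcan01_06094, Fcan01_06093, Fcan01_23701 and Fcan01_10135 were 3.11, 2.92, -1.66 and -0.74, none of them called. For cyproconazole the 18 genes became 4 and 8 without untreated library 1 and 2, and 11 and 7 without cyproconazole library 2 and 3. For both compounds the 13 genes became 0 and 4 without untreated library 1 and 2, and 5 and 7 without mixture library 1 and 3. These counts are edgeR's, and DESeq2 on all libraries called 43. In edgeR's fit of all libraries 656 of 16985 genes had an unadjusted p below 0.05, a share no higher than chance would give. With both compounds Fcan01_00867 lost its call without untreated library 1 (7.18), and Fcan01_00866 without untreated library 1 (6.97) or 2 (6.15). Without untreated library 3, the only untreated library with counts of Fcan01_00867, its fold has no upper bound, and it kept its calls with cyproconazole and with both compounds (edgeR adjusted p = 0.000591 and 0.00101).

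**Figure D3:**
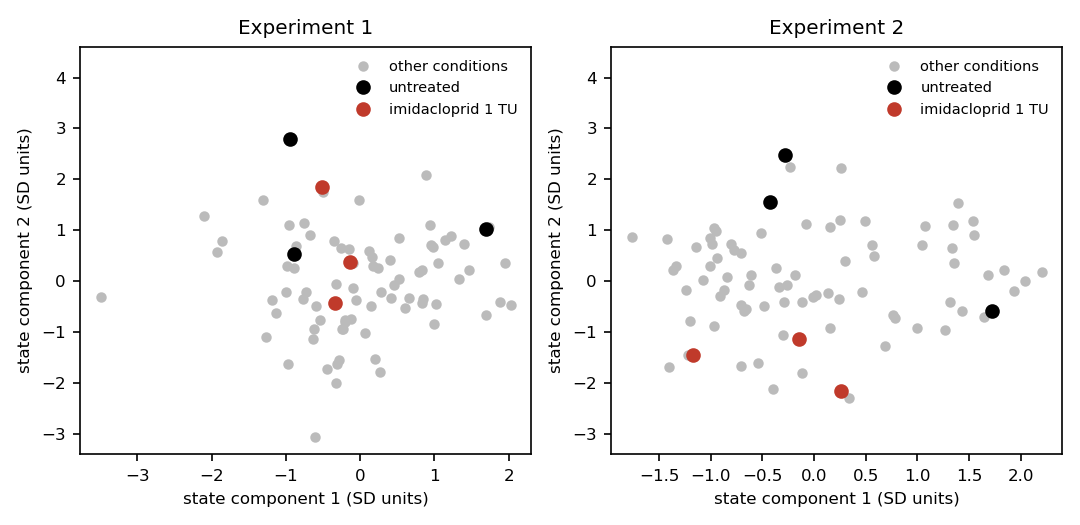
Scores of every library (points) on the 2 leading components of variation around the condition means, in SD units, with untreated libraries in black and 1 TU of imidacloprid alone in red. In experiment 2 the 3 imidacloprid libraries lie below 0 on the second component and untreated libraries 1 and 2 above 0.

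Libraries of 1 condition differed from each other along shared directions. Around the condition means, the 2 leading components held 24.7% and 12.7% of the variance in experiment 1 and 33.1% and 20.4% in experiment 2, and the planes they span in the experiments had canonical correlations of 0.913 and 0.762 across 16744 genes, which are not independent replicates. The 1 TU imidacloprid and untreated libraries of experiment 2 stood apart on the second component and overlapped on the first. Of the squared log2 changes between them, 66.6% lay along the 2 directions found in experiment 1. For the 26 other conditions against the same controls this share was 10.4% to 68.6%. A set of 302 genes was near silent in most libraries and high in 6 libraries of experiment 1 and 15 of experiment 2, at most 1 library in a condition. Their summed level was at most 40.2 CPM in the other libraries of experiment 1 and at least 343 CPM in the 6, and the figures for experiment 2 were 33.9 and 125 CPM. The highest sum, 1692 CPM, was in an untreated library. Across 84 libraries it had no relation to dose that passed a permutation test. Pearson's r with imidacloprid dose was -0.158 in experiment 1 and -0.125 in experiment 2 (Spearman's rho -0.0803 and -0.0968), and with clothianidin and cyproconazole -0.0584 and -0.0535 (rho -0.145 and -0.0129). The 4 permutation p values were 0.151, 0.257, 0.604 and 0.632 for r (adjusted 0.513, 0.513, 0.632 and 0.632) and 0.465, 0.381, 0.188 and 0.906 for rho (adjusted 0.620, 0.620, 0.620 and 0.906). Without the 2 libraries farthest from the median dose r was -0.158, -0.116, -0.0449 and -0.0327.

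**Figure D4:**
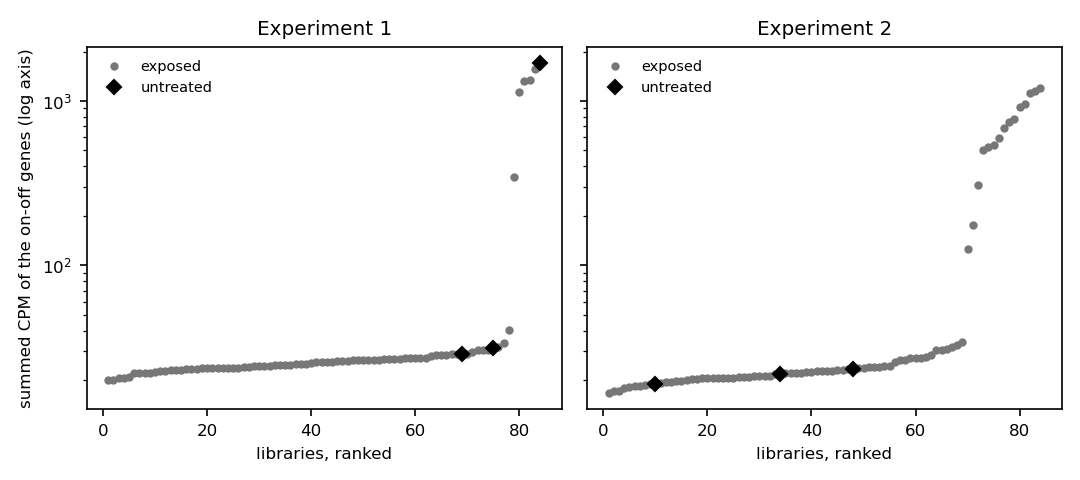
Summed CPM (log axis) of the 302 genes that are near silent in most libraries, with the 84 libraries of each experiment in rank order and untreated libraries as black diamonds. There are 6 libraries above the gap in experiment 1 and 15 in experiment 2, and the highest, at 1692 CPM, is untreated.

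Genes shared between compounds were counted in the same direction. Imidacloprid and clothianidin, whose slopes come from the same libraries, shared 78 genes, 8 rising and 70 falling, and 27 more went opposite ways. Independent lists would share 3.31 rising and 15.1 falling genes, and 99 regroupings of the libraries shared a mean of 0.859 and at most 63. Here and below, most regrouped lists were shorter than the real ones, which keeps their overlaps small. Across genes, which are not independent replicates, the slopes correlated at r = 0.0465 (regroupings -0.833 to 0.793) with a covariance of 0.00798 against 0.00490 under regrouping. From separate libraries r was 0.108 and the covariance 0.05003. Imidacloprid and cyproconazole shared 2 rising genes, where independent lists would share 0.106 and regroupings shared a mean of 0.121 and at most 7, more than the real 2, with r = 0.0732 (regroupings -0.643 to 0.732), a covariance of 0.00894 against 0.00350 and, from separate libraries, r = 0.0492 and a covariance of -0.0142. Between the experiments, which share no libraries, the imidacloprid slopes correlated at r = 0.359 (regroupings -0.692 to 0.603) with a covariance of 0.0433 against -0.00391. Fcan01_16176 and Fcan01_17273 rose with imidacloprid in both experiments and with clothianidin. Fcan01_17273 had slopes of 0.80, 0.84 and 0.38 (edgeR adjusted p = 1.08e-06, 0.0380 and 0.0180), and Fcan01_16176 had 0.64, 1.32 and 1.16 (edgeR adjusted p = 0.0476, 0.0456 and 1.87e-05). Fcan01_16176 lost its imidacloprid calls without the libraries numbered 1 (0.69 and 1.38), 2 (0.58 and 1.00) or 3 (0.67 and 1.62). Without those numbered 2 or 3, Fcan01_17273 lost its clothianidin call (0.36 and 0.31) and its call for imidacloprid in experiment 2 (0.67 and 0.83).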

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

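Some of the tests below were chosen after the results were seen, namely the state components as covariates, the spread under reassigned doses and all 3 tests of the on-off genes, while the others had their predictions written first. Between the experiments, 20 genes had a higher imidacloprid slope in experiment 2. Among those averaging at least 5 CPM the largest differences were those of Fcan01_24555 (2.09) and Fcan01_06718 (1.83), and 8 genes of lower level differed more. Of 60 regroupings of the libraries, the real one included, 5 gave as many calls, and the highest other gave 5850, so chance is not excluded for this count. A grouping that calls several times the real number points to a structure of the samples other than dose. The 97 genes with a product term of imidacloprid and clothianidin are in the same position, with 9 of 100 regroupings reaching that number and the highest other at 392. For imidacloprid with cyproconazole the real count was 0, which all 100 regroupings reach by definition, so the regroupings test nothing there (highest other 3548).

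The other trends stood out from most regroupings. For imidacloprid in experiment 1, 1 of 100 groupings, the real one, reached 387 calls, and the highest other gave 316. For clothianidin 2 of 100 reached 1692 (highest other 4944), for imidacloprid against clothianidin 2 of 100 reached 977 (highest other 2848), for imidacloprid in experiment 2 4 of 100 reached 11 (highest other 163), for cyproconazole 2 of 100 reached 278 (highest other 3755), and for imidacloprid against cyproconazole 1 of 100 reached 113 (highest other 82). The high counts of single regroupings, several times the real ones, again point to a structure of the samples.

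With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In experiment 1 the real split gave 60 calls for 1 TU of imidacloprid (highest other 1, reached by 1 split), 1164 for clothianidin (highest other 608, reached by 1) and 170 for both (highest other 1030, reached by 2). At matched doses of 0.2, 0.4, 0.6 and 0.8 TU the real split gave 3, 5, 7 and 25 calls and every other split 0, so that 1 split reached each, while at 1 TU it gave 9 and 3 splits reached it (highest other 20). In experiment 2 it gave 3159 for imidacloprid (highest other 2794, reached by 1), 18 for cyproconazole (highest other 3631, reached by 2) and 13 for both (highest other 1, reached by 1). The splits with 1030 and 3631 calls, several times the real counts, point to a structure of the samples.

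The 3159 genes called at 1 TU of imidacloprid in experiment 2, against 11 in the trend, may reflect library state. Of the squared log2 changes 66.6% lay along the state directions found in experiment 1, against 12.3% at 1 TU in experiment 1 and 10.4% to 68.6% for the 26 other conditions against the same controls. With the 2 state components as covariates 1 gene was called and the median change of the 3159 genes in the called direction fell from 0.97 to 0.15 (median SE 0.310 and 0.183), but the groups do not overlap on the second component (untreated -0.579 to 2.48, imidacloprid -2.16 to -1.14), so the covariates would take up a response to the dose as well and this fit decides nothing, a reading changed after its values were seen. An imidacloprid response at 1 TU should share its directions with experiment 1, but 36.5% of the genes (1150 of 3152) had the same sign there. This share lay under the bound set beforehand for no common response. In the trend over experiment 2, which shares the end libraries, 99.5% (3143 of 3159) had the same sign, which is no independent support. Genes vary together, so shares of like signs spread widely. For genes called with clothianidin they ran from 28.5% to 70.5% against imidacloprid slopes of regrouped libraries of experiment 2. That range is for other genes and for trends, and the spread for the 3159 genes at 1 TU was not measured. The 36.5% thus shows no repeat in experiment 1 and by the bound argues against a common response. Without its own spread it does not exclude one. State, which the share along its directions goes with, and a response limited to experiment 2 stay open too.

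The 302 on-off genes, near silent in most libraries, did not need a pesticide dose, since the highest sum, 1692 CPM, was in an untreated library. If 1 source of extra RNA, such as another organism or a body part, gave rise to them, their proportions should be constant. A gene's share varied by a median of 0.358 between the 21 high libraries (79 genes), counting error included. Chi-square per degree of freedom of these shares was 8.1, so they varied by more than counting error. A source of varying make-up could also give this, so that explanation stays open. By order of listing, 3, 1 and 11 of 28 libraries per place were high in experiment 2 (Fisher's exact p = 0.00168) and 2, 2 and 2 in experiment 1 (exact p = 1). The order may stand for a step of handling that the labels do not give, and that too stays open. Places by sample number, which can differ from places in the listing, were not tested.

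Imidacloprid changed 387 genes in experiment 1 and 11 in experiment 2. A larger spread between libraries could have hidden the same response. Slopes of genes called without 1 library per condition should then be as large in experiment 2 as in the left-out libraries of experiment 1. In 2 of the 3 rotations the genes held in the left-out libraries (98.7% and 100% with the same sign) and the ratios, 0.142 and 0.233, lay under the bound of 0.5 set beforehand for a real difference. In slope, experiment 2 lay 0.286 and 0.326 below that bound, but the 95% intervals from the spread under reassigned doses reach 0 (-0.700 to 0.128 and, by little, -0.653 to 0.00208), and rising genes (0.77 in experiment 2 in both, against 1.02 and 0.84) kept more of their slope than falling ones (0.09 and 0.12, against 0.73 and 1.23). In the other rotation the 626 genes called did not hold in the left-out libraries (median -0.06, against 0.29 in experiment 2), which leaves no slope to compare with, and for these reasons, seen only with the values, a larger spread (standard errors 1.17 times as large) was left open. Library state as the whole cause was examined by the fit with state covariates, chosen after the result. It called 32 genes in experiment 2 and 369 in experiment 1, so the counts stayed apart. Most of the median slope of the genes called without the covariates was kept (0.99 of 1.32 and 0.68 of 0.85). The covariates can take up a response to the dose as well, so this fit leaves state open.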

How the results depend on the processing

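Chosen after the values were seen were the fits with 2 state components, with the place in the listing as a block, without far libraries, without high on-off libraries and on counts summed per condition. Alternatives kept the direction of nearly all named genes and changed the counts of genes far more. Of 1033 values of named genes under alternatives, 790 kept direction and threshold and 242 lost the threshold. The 1 reversal was Fcan01_06718, whose imidacloprid slope difference between experiments was -0.00240 without the libraries numbered 1 (adjusted p = 0.995) and up to 2.41 without the others, against 1.83 with all. Of 324 counts under alternatives, 151 stayed within 1.5 times the reported count and 173 moved further. The cause was not tested except where stated above.

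Leaving out 28 libraries with the same number gave 63 to 764 genes for imidacloprid in experiment 1 (387 with all), 593 to 1169 for clothianidin (1692), 123 to 1311 for imidacloprid against clothianidin (977), 2 to 326 for their product term (97), 5 to 26 for imidacloprid in experiment 2 (11), 106 to 403 for cyproconazole (278), 63 to 72 for imidacloprid against cyproconazole (113), 0 to 0 for their product term (0) and 1 to 2354 for the difference between experiments (20). Leaving out 1 library gave 19 to 75 at 1 TU of imidacloprid in experiment 1 (60), 367 to 1508 with clothianidin (1164) and 78 to 259 with both (170), 0 to 3 for imidacloprid against clothianidin at 0.2 TU (3), 1 to 12 at 0.4 TU (5), 1 to 4 at 0.6 TU (7), 3 to 18 at 0.8 TU (25) and 6 to 63 at 1 TU (9). In experiment 2 it gave 0 to 7404 with imidacloprid at 1 TU (3159), 4 to 25 with cyproconazole (18) and 0 to 17 with both (13).

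The first residual component as a covariate, planned, raised most counts. They became 873 (206 higher, 667 lower) for imidacloprid, 2802 for clothianidin, 2416 (694 and 1722) for their difference and 447 (220 and 227) for the product term in experiment 1, 339 (237 and 102), 3886 (2239 and 1647) and 661 at 1 TU of imidacloprid, clothianidin and both, and 222, 698, 329, 850 and 85 at the 5 matched doses. In experiment 2 they became 26 for imidacloprid, 1032 (330 and 702) for cyproconazole, 783 (633 and 150) for their difference, and 5183 (2286 and 2897), 43 and 78 at 1 TU of imidacloprid, cyproconazole and both. Overlaps became 145 for imidacloprid with clothianidin, 13 for imidacloprid in both experiments, 6 for imidacloprid with cyproconazole, 312 for clothianidin with cyproconazole and 6 for the triple overlap. This fit was not run for the difference between experiments. Its covariate has the same mean in every condition, so it lowers the spread within conditions but cannot account for a state difference between them. The higher counts are thus no support for the calls.

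With the 2 state components as covariates imidacloprid in experiment 1 gave 369 genes (127 higher, 242 lower) and its difference from clothianidin 709 (347 and 362). The product term gave 531, the 1 TU comparisons 392, 1834 and 801, and the matched doses 12, 23, 21, 46 and 69. Experiment 2 gave 32 (20 and 12) for imidacloprid, 1032 (417 and 615) for cyproconazole, 335 for their difference, and 1, 44 and 62 at 1 TU. The difference between experiments gave 13, and the overlaps, in the order above, were 118, 18, 8, 327 and 9.

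DESeq2 gave 146 genes (71 and 75) for the product term in experiment 1, 124 and 297 at 1 TU of imidacloprid and of both, 26, 18, 130 and 33 at matched doses of 0.4, 0.6, 0.8 and 1 TU, 474 (194 and 280) for cyproconazole, and 28 and 43 at 1 TU of cyproconazole and of both. Without the 7 libraries far from the rest, an addition, the product term gave 8, the 1 TU comparisons of experiment 1 gave 34, 126 and 112, the matched dose of 0.4 TU 17, cyproconazole 169, both compounds at 1 TU in experiment 2 4, the overlap of clothianidin with cyproconazole 41 and the triple overlap 0. Without the 1 TU conditions imidacloprid against clothianidin gave 2121, their product term 154, imidacloprid in experiment 2 5, the difference between experiments 9, the overlap of imidacloprid in both experiments 5, that of imidacloprid with cyproconazole 4 and the triple overlap 0. Without the libraries high in the on-off genes, an addition, the product term gave 32, imidacloprid in experiment 2 7 and cyproconazole 116.

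On counts summed per condition, also added, imidacloprid in experiment 1 gave 83, the product term 7 and imidacloprid in experiment 2 5, with overlaps of 15 for imidacloprid and clothianidin, 5 for imidacloprid in both experiments, 1 for imidacloprid and cyproconazole, and 0 for the triple overlap. Without the low-count filter imidacloprid gave 20 in experiment 2 and 5 at 1 TU, and the difference between experiments gave 33. Any exposure against none gave 2450 for imidacloprid in experiment 1, 2 for imidacloprid in experiment 2 and 92 for cyproconazole. The product of doses in the model gave 174 for imidacloprid in experiment 1 and 76 for cyproconazole. Dose as 6 classes gave 1005 for clothianidin, 6 for imidacloprid in experiment 2 and 129 for cyproconazole. Single-compound series gave 47 and 608 for imidacloprid and clothianidin in experiment 1, and 3 and 3 for imidacloprid and cyproconazole in experiment 2. With only the 2 groups compared, the 1 TU comparisons gave 2, 0 and 0 in experiment 1 and 0, 0 and 0 in experiment 2, and the matched doses from 0.2 to 0.8 TU gave 0, 9, 0 and 359. Relative log expression changed no count by more than 1.5 times, with 395 genes for imidacloprid and 1734 for clothianidin in experiment 1.

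The labels number samples across the whole series, in a run of numbers with gaps for each condition. They do not call any number a replicate, so they state no pairing of libraries. The place of a sample's number within its run can differ from its place in the listing, and it was not tested. With the place in the listing as a replicate block no count changed by more than 1.5 times (348 genes for imidacloprid and 1709 for clothianidin in experiment 1, 11 and 261 for imidacloprid and cyproconazole in experiment 2, 2972 at 1 TU of imidacloprid there, 17 for the difference between experiments). The block ended the calls of Fcan01_01275 for cyproconazole (-1.81, edgeR adjusted p = 0.0617), Fcan01_08259 for imidacloprid against cyproconazole (1.86, edgeR adjusted p = 0.0585) and Fcan01_06718 between experiments (1.33, edgeR adjusted p = 0.191). Libraries at the same place deviated from their condition means with a mean correlation of 0.0152 in experiment 1 and 0.00730 in experiment 2 (permutation p = 0.1 and 0.345 for the share of variance held by place). Gene-list alternatives (camera with an estimated correlation, and fry) were not run since no list was formed.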

Other observations

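Clothianidin in experiment 1 and cyproconazole in experiment 2, which share no libraries, called 71 genes in the same direction, 47 rising and 24 falling, and 8 in opposite directions. Independent lists would share 8.23 rising and 5.34 falling genes, and 99 regroupings of the libraries shared at most 1. Most regrouped lists were shorter than the real ones, which keeps their overlaps small. Independent lists leave out the directions of variation that the experiments share. Neither is therefore a full test of the 71 genes. The number shared was 312 with the first residual component and 327 with the 2 state components as covariates, and 41 without the libraries far from the rest. The first residual component cannot account for a state difference between conditions. In sign the sharing was not particular to this pair, since the 1663 clothianidin genes had the same sign in 74.0% of the cyproconazole and 74.1% of the imidacloprid slopes of experiment 2 (at most 72.8% and 70.5% in 99 regroupings, a test chosen after these shares had been seen). Fcan01_20268 had slopes of 1.53 with clothianidin (SE 0.181, edgeR adjusted p = 2.92e-09) and 2.53 with cyproconazole (SE 0.252, edgeR adjusted p = 4.68e-13), and Fcan01_17604 had 1.48 and 4.58 (edgeR adjusted p = 3.83e-06 and 1.15e-15). Among falling genes Fcan01_26995 had slopes of -2.23 and -1.40 (edgeR adjusted p = 8.04e-09 and 0.00684). These genes were chosen after their values had been seen. Over 16744 genes, which are not independent replicates, the slopes correlated at r = 0.396, inside the range of regroupings (-0.654 to 0.761), with a covariance of 0.0595 against -0.00208 under regrouping.

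Called genes lay beside each other in the numbering of identifiers. For clothianidin 156 pairs of consecutive identifiers were called in the same direction, against a mean of 64.6 and a maximum of 95 in 10000 random sets (permutation p = 1e-04, the smallest these sets can give). For cyproconazole 19 pairs were called, against a mean of 1.75 and a maximum of 9 (permutation p = 1e-04), Fcan01_00866 and Fcan01_00867 among them. The tests of neighbours were set before their values were seen. If consecutive numbers stand for neighbours in the genome, clusters of related genes that respond together could give such pairs. Consecutive genes that were not called correlated across libraries at a median r of 0.106 in experiment 1 and 0.136 in experiment 2, against 5.96e-05 and 0.00116 for random pairs, so a state shared by neighbours could add to the pairs of both compounds, and the test leaves that open.

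A hypothesis for a marker of imidacloprid rests on the 5 genes Fcan01_17957, Fcan01_10767, Fcan01_17452, Fcan01_08638 and Fcan01_01431, which were called in both experiments under each of the 11 alternatives counted together. With any exposure against none, which called 2 genes in experiment 2, Fcan01_17957 (0.93) and Fcan01_17452 (0.91) were not called there (edgeR adjusted p = 0.239 for both). Fcan01_17957 had an imidacloprid slope of 2.81 in experiment 1 with the product of doses in the model, and its slopes for clothianidin (-0.42, edgeR adjusted p = 0.0547) and cyproconazole (0.57, edgeR adjusted p = 0.198) were not called. The set is not specific to imidacloprid, since Fcan01_17452 and Fcan01_01431 also rose with cyproconazole (1.14 and 0.80, edgeR adjusted p = 0.000792 and 0.0222) and their slopes for the 2 compounds were not called different (edgeR adjusted p = 0.552 and 0.531). Such a marker could be tested by measuring these genes at doses below 0.2 TU and with other neonicotinoids. Fcan01_00867 and Fcan01_00866 are candidates for cyproconazole, with slopes of 6.75 and 6.40. In the cyproconazole-only series their slopes were 6.59 and 6.80 and neither was called (edgeR adjusted p = 0.278 and 0.0954). They could be tested by measuring both genes along doses of cyproconazole alone, with more libraries per dose, and with other azoles.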
